A study of Mus musculus with 20 samples.

How the data were processed

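RNA was measured in mouse bone marrow cells sorted as lineage-negative, cKit-positive and Sca1-positive (LSK cells), a fraction that holds haematopoietic stem cells and multipotent progenitors. Per the labels the mice were C57Bl/6J of 3 to 4 months, each library was total RNA from a pool of 2 mice, and 4 pools were sequenced in each of 5 groups: wild type with Vav-Cre (WT), Idh1R132H, Idh2R140Q and Idh2R172K, each a conditional allele with Vav-Cre, and Tet2 knockout (Tet2KO). The label of Tet2KO gives no Cre, and no label says which exons of Tet2 were removed. Per the labels the authors trimmed reads with Trim Galore, aligned them to mm10 with STAR and counted them with featureCounts. They give no versions, no annotation release and no strand setting.

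The deposited values are TPM, transcript abundances corrected for gene length, in 1 table of 46078 Ensembl gene IDs and 20 libraries in which each library sums to 1000000. Columns were matched to samples by mutation and pool number. The columns matched to Idh2R140Q carry a prefix naming Idh1 together with the mutation 140Q, and they were assigned by that mutation. Gene symbols, coordinates and exon lengths come from GENCODE M21 on mm10. Of the IDs, 45143 were found there and 935 were not, and the latter held 0.103 to 0.128% of the TPM of a library.

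The depth was read from the TPM. For each library a factor was sought that turns TPM times exon length into whole numbers, and 42700 genes were returned to read counts in this way. Of these counts 90.0 to 91.0% of the low values per library, up to 30 reads, were whole within 0.1 reads. At the gene level 87.5% of genes with values up to 60 reads were whole. The depths found this way are 35.2 to 45.04 M assigned reads per library (M, 1000000), with a median of 39.2 M. The rebuilt counts served depth and 1 alternative, and all reported values rest on TPM.

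The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with 1 fit of all 5 groups, moderated variances with an intensity trend, and 2-sided p-values adjusted by Benjamini and Hochberg over the 14176 genes with a mean of at least 1 TPM. A gene counts as called at an adjusted p under 0.05. Log2 differences are given with the standard error (SE) of the fit, and TPM as mean and SD over n = 4 libraries. All 10 pairwise comparisons were made, and each mutant group was compared with the same 4 WT libraries. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

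There were 34 gene lists. The 21 lists of processes were HSC, lymphoid priming, granulocyte-monocyte priming, erythroid priming, megakaryocyte priming, S phase, G2/M phase, interferon response, NF-kB inflammatory response, immediate early and heat shock, TET with DNMT and base excision, other 2-oxoglutarate dioxygenases, IDH with the TCA cycle and 2-oxoglutarate metabolism, HIF and glycolysis, p53 targets, DNA damage response, haematopoietic and leukaemia transcription factors, haem synthesis and iron, ribosomal proteins, nuclear oxidative phosphorylation, and MHC class I presentation. The 13 marker lists were mature neutrophil, B lineage, T and NK, dendritic and MHC class II, basophil and mast, red cell, macrophage, stroma and endothelium, eosinophil, plasma cell, sex-linked, mitochondrial transcripts, and replication-dependent histones. Each list was tested with camera in limma at its preset inter-gene correlation, which asks whether the list moved relative to all other genes, and p-values were adjusted over the 34 lists of a comparison. The test was repeated with an estimated correlation, and with fry, which asks whether the members moved on balance in either direction. Members passing the test are counted over all genes and, separately, adjusted over the list alone.

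The groups, the main test, the lists and the rule for naming genes were fixed before the data were examined. The rule names Idh1, Idh2 and Tet2 in every group. For each mutant against WT it names the 10 largest rises and the 10 largest falls among called genes whose 4 mutant libraries lie all above or all below the 4 WT libraries. Between mutants it takes 5 of each. It adds up to 4 called members of each list with the smallest p, gives values for Procr, Hlf, Flt3, Mpo, Gata1, Itga2b and Mki67, and leaves sex-linked and unnamed gene models out of the largest changes. Where no gene was called, it gives the 5 smallest p as values. The genes described in full were picked among those the rule names, mostly for calls that held when any single library was left out, which was seen in the data. Not all genes the rule names are printed. Any gene outside it is said to be so.

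Alternatives planned in advance were a pseudocount of 0.1, no filter, a mean of at least 5 TPM, median-of-ratios and quantile scaling, TPM rescaled without mitochondrial, histone and the 20 most abundant genes, a fit of only the 2 groups compared, library weights, no variance trend, the replicate number as a block, and leaving out each library in turn. Added after seeing the data were removal of the exon length trend in each library over 20 length classes, limma-voom on the rebuilt counts, the sex of the pool as a covariate, the immediate early list score as a covariate, leaving out the number 4 libraries of WT and the Idh groups, and leaving out these and Tet2KO replicate 2. The replicate numbers of the labels were checked by correlating the deviations of same-number libraries from their group means. They pair the libraries, with every r over 0.1, in Idh1R132H against WT (0.176 to 0.489) and among the Idh groups (0.147 to 0.538). Idh2R140Q against WT just missed this (0.097 to 0.451), while Idh2R172K against WT (-0.023 to 0.404) and the Tet2KO comparisons did not pair. No label says what a number shares, but 1 and 3 were female and 2 and 4 male in WT and Idh. The procedure was tested on simulated data with 200 changed genes among 13577 in each of 10 sets. It found 35.7, 66.4 and 87.9% of genes changed by 1.5, 2 and 4-fold for Idh2R172K against WT, and 34.9, 68.8 and 89.5% for Tet2KO against WT. False calls made up 4.40 and 5.72% of all calls, and 1 list shifted on purpose was called in 10 of 10 sets. Unchanged groups were simulated in 100 draws from the residuals of each group. Genes withheld for evaluation are not reported here by name, though they stay in the list counts.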

Results

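Total RNA of sorted LSK cells was sequenced in 20 libraries, each from a pool of 2 mice, with n = 4 pools in each of 5 groups. The assigned reads per library, recovered from the TPM values and given in M (1000000 reads), averaged 40.0 M (SD 3.10) in WT, 41.1 (SD 2.82) in Idh1R132H, 40.8 (SD 2.87) in Idh2R140Q, 40.8 (SD 2.09) in Idh2R172K and 36.9 (SD 1.23) in Tet2KO. Each group held 2 pools whose sex-linked RNA was male and 2 whose RNA was female. Vav-Cre acts in blood-forming cells, so the WT group controls for the recombinase in the Idh groups, while the Tet2KO label names no Cre. A difference in Cre, if there is one, is thus not separated from the loss of Tet2 in any comparison with Tet2KO. The single most abundant gene, the rRNA-like Gm23935, took 7.55 to 20.0% of TPM (median 11.9%). Libraries with the number 4 in WT and the Idh groups lay at the low end of this share, at 7.55 to 8.13%, and Tet2KO replicate 2 at the top. These 5 libraries also stood apart in other measures, which are given beside the results they touch.

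**Figure D1:**
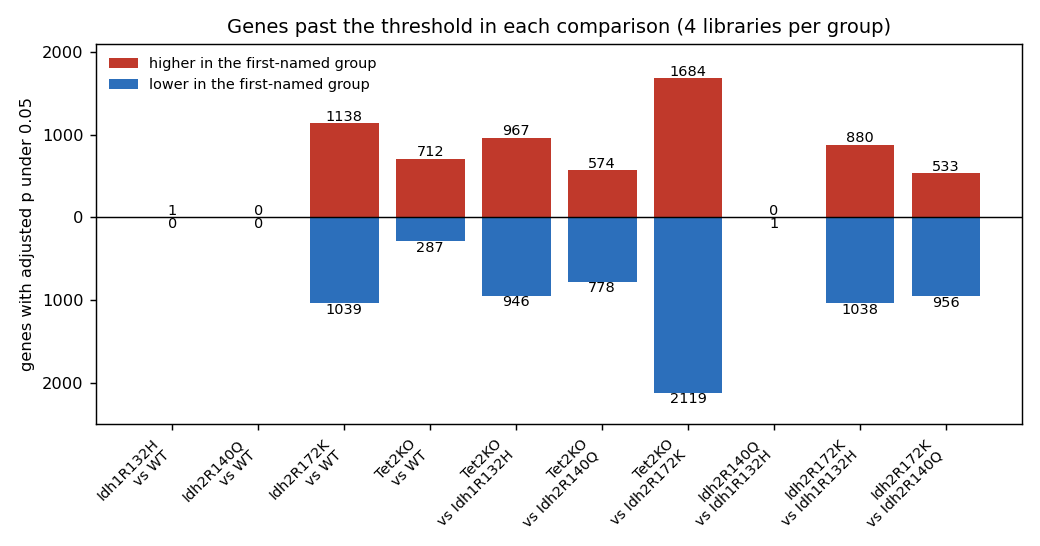
Number of genes called higher (bars up) and lower (bars down) by limma at an adjusted p under 0.05 in each of the 10 pairwise comparisons, over 14176 genes and n = 4 libraries per group. Idh2R172K and Tet2KO differed from every other group by 999 genes or more, and Idh1R132H, Idh2R140Q and WT differed among themselves by 1 gene or 0.

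The targeted genes came first. Idh2, which encodes the mitochondrial NADP-dependent isocitrate dehydrogenase (ENSMUSG00000030541, chromosome 7, 80094846 to 80115392, mm10), rose in Idh2R172K by 0.83 ± 0.11 (log2 ± SE, adjusted p = 2.4e-05), from 529 TPM (SD 80.6, n = 4) in WT to 937 (SD 62.8, n = 4). All alternatives kept this call. In Idh2R140Q, whose allele lies in the same gene, the Idh2 difference was 0.02, and it was 0.12 in Tet2KO. Idh1, the cytosolic enzyme (ENSMUSG00000025950, chromosome 1, 65158616 to 65186500), was at 104 TPM (SD 17.5, n = 4) in Idh1R132H and 88.8 (SD 12.2, n = 4) in WT, a log2 difference of 0.22 ± 0.16 that was not called. Tet2, which encodes a 2-oxoglutarate-dependent dioxygenase that oxidises 5-methylcytosine (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139), rose in Idh2R172K by 0.71 ± 0.20 (adjusted p = 0.0188), from 7.5 TPM (SD 1.17, n = 4) to 12.9 (SD 1.61, n = 4). That call ended without WT replicate 2 (0.0562), WT replicate 3 (0.0533), Idh2R172K replicate 2 (0.058) or Idh2R172K replicate 4 (0.0575). In Tet2KO the Tet2 gene stood at 9.91 TPM (SD 2.85, n = 4) and its log2 difference from WT was 0.33 ± 0.20 (adjusted p = 0.295). A value summed over the gene neither checks nor contradicts the knockout label, since the deleted exons are not stated and the rest of the gene can still be transcribed.

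Idh1R132H against WT asks what the mutant cytosolic enzyme, which makes 2-hydroxyglutarate, does to the RNA of LSK cells. A single gene was called. Fhl2, which encodes a LIM domain cofactor of transcription (ENSMUSG00000008136, chromosome 1, 43123074 to 43196984), rose by 1.48 ± 0.18 (adjusted p = 0.00261), from 1.98 TPM (SD 0.712, n = 4) to 7.18 (SD 0.947, n = 4). At an unadjusted p under 0.05 there were 229 genes in limma. The Fhl2 call ended in the fit of the 2 groups alone (adjusted p = 0.128), and a mean of at least 5 TPM removed the gene. With the replicate block Plbd1, chosen after its value was seen, made 2 genes.

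As sets, 9 lists were higher and 5 lower in Idh1R132H, and none of these calls held with an estimated correlation. The interferon response list was above 0 in 36 of 38 members with a median of 0.28 (camera adjusted p = 3.45e-23; adjusted p = 0.295 with an estimated correlation). No member passed over all genes, and 5 passed adjusted over the list alone. Erythroid priming, the early red cell programme, was above 0 in 20 of 23 members with a median of 0.20, or 0.13 without WT replicate 1 (camera adjusted p = 5.16e-06; adjusted p = 0.302 with an estimated correlation), with no member adjusted over the list alone. The dendritic and MHC class II markers had a median of 0.39 with 8 of 11 above 0 (camera adjusted p = 6.7e-06; adjusted p = 0.295 with an estimated correlation). The basophil and mast markers had a median of 0.20, or 0.11 without Idh1R132H replicate 1 (camera adjusted p = 0.00144; adjusted p = 0.302 with an estimated correlation). Adjusted over the list alone 1 and 2 members of these passed. The HSC list of stem cell genes had 10 of 33 members above 0 and a median of -0.05 (camera adjusted p = 0.00144; adjusted p = 0.84 with an estimated correlation). That median was -0.10 to 0.01 without WT replicate 3 or 4 or Idh1R132H replicate 2 or 4.

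Idh2R140Q against WT asks the same of the first mitochondrial mutant. No gene was called by limma (407 at an unadjusted p under 0.05), and limma-voom called 0 as well (415 unadjusted). The 5 smallest p in limma belonged to Ighv1-25 (1.17 ± 0.23, adjusted p = 0.869), Mir1938 (1.53), Hddc3 (0.95), Hm629797 (0.91) and Afp (-0.49, adjusted p = 0.998). Without the filter on low values 2 genes passed, Hapln3 and Gm14248, which were chosen after their values were seen.

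Among the lists, 5 were higher and 8 lower in Idh2R140Q, none with an estimated correlation, and no member of any list passed, over all genes or adjusted over the list alone. Lymphoid priming genes were above 0 in 22 of 24 members with a median of 0.24, or 0.40 without WT replicate 4 and 0.16 without Idh2R140Q replicate 4 (camera adjusted p = 7.9e-05; adjusted p = 0.777 with an estimated correlation). Granulocyte-monocyte priming genes had a median of -0.12 with 8 of 31 above 0 (camera adjusted p = 1.18e-05; adjusted p = 0.777 with an estimated correlation). Small shifts below 0 ran through the nuclear oxidative phosphorylation genes (3 of 79 above 0, median -0.12, camera adjusted p = 1.5e-23), the ribosomal proteins (2 of 85 above 0, median -0.11, 1.47e-19) and the S phase genes (4 of 30 above 0, median -0.05, 9.75e-07), each with an adjusted p = 0.777 with an estimated correlation. For granulocyte-monocyte priming the median was -0.24 to -0.05 without WT replicate 2 or 4 or any Idh2R140Q replicate, and for oxidative phosphorylation -0.18 without WT replicate 4 and -0.05 without Idh2R140Q replicate 4. For ribosomal proteins it was -0.19 to -0.01 without WT replicate 2 or 4 or Idh2R140Q replicate 1 or 4, and for S phase -0.10 to -0.01 without WT replicate 1 or 4 or Idh2R140Q replicate 2, 3 or 4. With the immediate early score as a covariate, added after seeing the data, the ribosomal call ended.

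Idh2R172K against WT asks what the other mitochondrial mutant does, and here the RNA of LSK cells changed widely. The red cell programme fell, with its main transcription factors Klf1 going from 55.7 to 7.74 TPM and Gata1 from 49.0 to 9.45. Of the granulocyte-monocyte genes 18 of 31 fell and 1 rose, though that list call did not hold with an estimated correlation (adjusted p = 0.521), while the integrin Itga2b and the adhesion molecule Selp rose. In all 2177 genes were called, 1138 higher and 1039 lower, of which 257 and 413 by at least 2-fold. The share of higher genes, 52.3%, was 44.9% with median-of-ratios scaling, 44.8% without the length trend, 64.5% with library weights and 67.7% without the number 4 libraries and Tet2KO replicate 2. It was 44.1 to 56.0% with single libraries left out.

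The rule named 10 rises. Perp, a tetraspan membrane protein and p53 target (ENSMUSG00000019851, chromosome 10, 18845020 to 18857073), rose by 3.77 ± 0.18 (adjusted p = 5.45e-11), from 6.03 TPM (SD 0.613, n = 4) to 94.8 (SD 10.4, n = 4). Smagp rose from 2.70 to 29.6 TPM, Cd200r4, a receptor of the CD200 family, from 2.00 to 22.4, Fhdc1 from 2.28 to 23.2, and Spats2 from 0.196 to 6.66. The other rises were Mir7007 and the immunoglobulin genes Igkv3-5 (5.65 ± 1.36), Ighv1-22, Igkv14-111 and Ighg2c. Of these, Ighv1-22 was lost without Idh2R172K replicate 2 (adjusted p = 0.0517) or without the number 4 libraries, and Ighg2c in the fit of the 2 groups. Igkv14-111 was lost without WT replicate 1, 2 or 3 or Idh2R172K replicate 2, 3 or 4 (0.061 to 0.142).

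Of the 10 falls, Padi4, which encodes an enzyme that converts arginine to citrulline (ENSMUSG00000025330, chromosome 4, 140745865 to 140774236), fell by 4.5 ± 0.17 on the log2 scale (adjusted p = 7.6e-12), from 50.1 TPM (SD 3.77, n = 4) to 1.27 (SD 0.331, n = 4). Car1, the carbonic anhydrase of early erythroid progenitors (ENSMUSG00000027556, chromosome 3, 14766216 to 14808368), fell by 4.36 ± 0.25 (adjusted p = 7.21e-10), from 499 TPM (SD 81.0, n = 4) to 25.2 (SD 10.7, n = 4). Nr0b2, an orphan nuclear receptor (ENSMUSG00000037583, chromosome 4, 133553376 to 133556536), went from 18.0 to 0.382 TPM (adjusted p = 1.11e-12). Chdh, the choline dehydrogenase of mitochondria, went from 35.1 to 0.725 TPM, Fbp1, an enzyme of gluconeogenesis, from 45.3 to 2.15, and the chemokine Ccl3 from 58.8 to 2.23. The others were Psma8, Ces2g, Gdf3 and Igkv6-32, the last lost with limma-voom.

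Erythroid priming was the list result that held in all alternatives tried. Of 23 measured members 17 fell and 1 rose, and adjusted over the list alone 21 fell and 2 rose. The median was -1.20 (camera adjusted p = 4.6e-26), and the call held with an estimated correlation (adjusted p = 0.00424). Klf1 (ENSMUSG00000054191, chromosome 8, 84901928 to 84905291) fell by 2.70 ± 0.12 (adjusted p = 2.9e-11), from 55.7 TPM (SD 6.28, n = 4) to 7.74 (SD 1.02, n = 4). Gata1 (ENSMUSG00000031162, chromosome X, 7959260 to 7978071) fell by 2.26 ± 0.12 (adjusted p = 5.09e-10), from 49.0 TPM (SD 5.25, n = 4) to 9.45 (SD 1.41, n = 4). Sphk1, a sphingosine kinase, fell by 2.83 ± 0.14. The member that rose was Cnrip1 (1.17), named after its value was seen. Haem synthesis and iron genes had 5 falls and 1 rise among 26 (6 and 1 adjusted over the list alone, camera adjusted p = 0.00294; adjusted p = 0.596 with an estimated correlation). Alad fell by 0.93, and the ferritin chain Fth1 went from 4285 to 2597 TPM. Red cell markers, which report mature cells, were not called as a list (2 of 11 fell, camera adjusted p = 0.186, fry adjusted p = 0.00706).

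**Figure D2:**
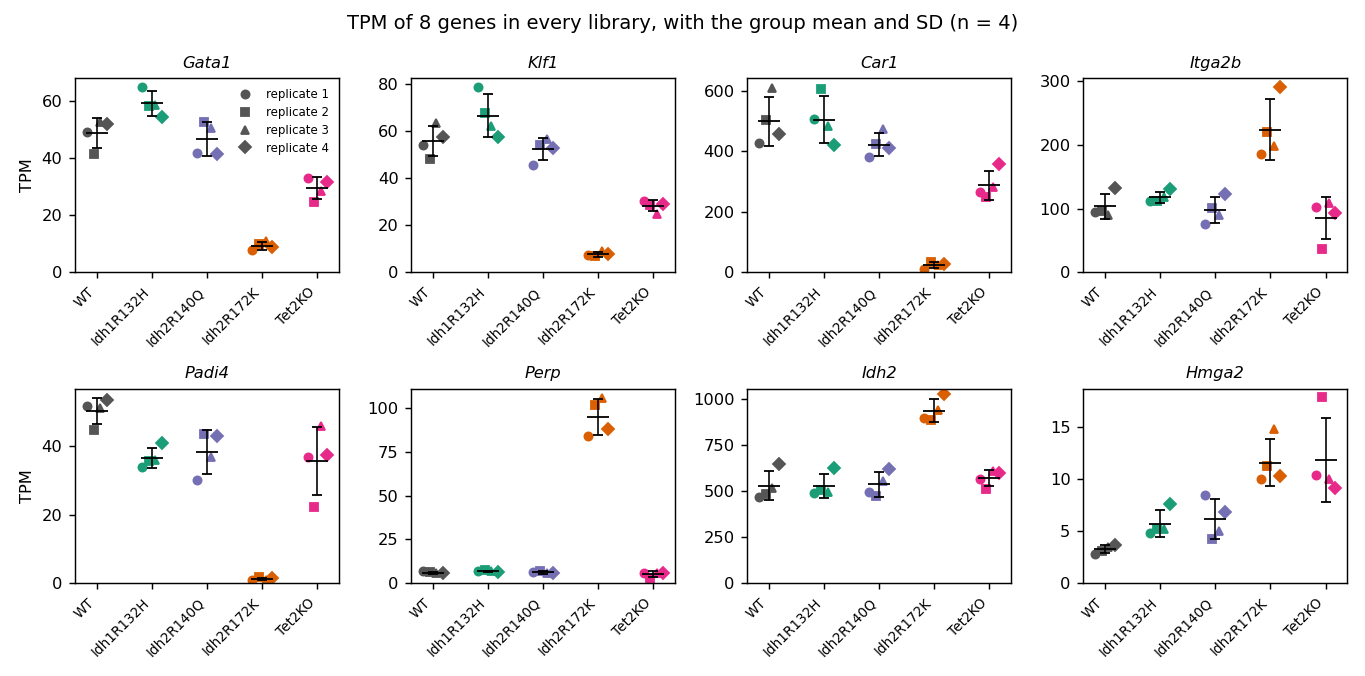
TPM of Gata1, Klf1, Car1, Itga2b, Padi4, Perp, Idh2 and Hmga2, genes chosen after seeing the data, in the 4 libraries of each group (points, shaped by replicate number), with the group mean (line) and SD (bar, n = 4). Gata1 averaged 49.0 TPM in WT, 9.45 in Idh2R172K and 29.5 in Tet2KO.

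Myeloid and lymphoid programmes were lower in Idh2R172K as well. Granulocyte-monocyte priming had 18 falls and 1 rise among 31 members (20 and 3 adjusted over the list alone) and a median of -0.74 (camera adjusted p = 1.8e-10; adjusted p = 0.521 with an estimated correlation). Ctsg, which encodes cathepsin G, went from 965 TPM (SD 138, n = 4) to 230 (SD 53.6, n = 4), Hk3 fell by 2.30 ± 0.18, and Trem3 fell by 2.51 ± 0.28. The primary granule enzyme Mpo stood at 2444 TPM (SD 278, n = 4) against 3608 (SD 694, n = 4) and was not called (adjusted p = 0.0759). Lymphoid priming had 9 falls and 2 rises among 24 members (11 and 3 adjusted over the list alone) and a median of -0.30, or -0.18 without Idh2R172K replicate 1 (camera adjusted p = 0.000401; adjusted p = 0.624 with an estimated correlation). Dntt, the terminal transferase of lymphoid progenitors, went from 916 TPM (SD 179, n = 4) to 232 (SD 26.1, n = 4), and Cd27 fell by 0.89 ± 0.14, while Tespa1 rose by 0.98. Flt3, the receptor of multipotent and lymphoid-primed progenitors, was at 160 TPM (SD 25.0, n = 4) against 267 (SD 58.8, n = 4), a log2 difference of -0.73 with an adjusted p of 0.0122.

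Stem cell and megakaryocyte genes split. The HSC list had 6 rises and 3 falls among 33 members, the same numbers adjusted over the list alone, and was not called (camera adjusted p = 0.404). Esam rose by 1.19 ± 0.22 and Mycn by 1.16 ± 0.22, while Prdm16, a regulator of stem cell maintenance, fell by 1.78 ± 0.18. Procr stood at 31.4 TPM against 26.1 and Hlf at 67.9 against 72.6. Megakaryocyte priming had 5 rises and 3 falls among 23 (7 and 3 adjusted over the list alone; camera adjusted p = 0.429). Selp went from 40.5 TPM (SD 14.9, n = 4) to 195 (SD 26.5, n = 4) and Itga2b from 104 TPM (SD 19.6, n = 4) to 224 (SD 47.4, n = 4), whereas the platelet chemokine Pf4 went from 160 to 46.8 TPM and Cavin2 fell by 1.65 ± 0.24. Haematopoietic transcription factors had 8 rises and 3 falls among 46 (12 and 3 adjusted over the list alone; camera adjusted p = 0.223), with Irf8, which directs dendritic and monocyte fate, down by 1.29 ± 0.19.

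Antigen presentation and several lists of mature cell markers went with these falls. B lineage markers (4 rises and 2 falls among 11, camera adjusted p = 0.377) and stroma markers (0.414) did not, with scores of 0.06 to 0.85 and 0.21 to 0.63 in Idh2R172K against -0.43 to -0.12 and -0.28 to 0.03 in WT. The dendritic and MHC class II markers had 4 falls and 1 rise among 11 (5 and 1 adjusted over the list alone) and a median of -0.75 (camera adjusted p = 0.0011; adjusted p = 0.547 with an estimated correlation). H2-Ab1, a chain of MHC class II, went from 213 TPM (SD 43.6, n = 4) to 83.0 (SD 14.9, n = 4). T and NK markers had 5 falls and 1 rise among 9 (6 and 1 adjusted over the list alone) and a median of -0.76 (camera adjusted p = 0.00207; adjusted p = 0.547 with an estimated correlation). That call ended with no filter and at a mean of at least 5 TPM. The kinase Lck, part of that list, went from 45.1 to 9.37 TPM. Macrophage markers had 2 falls among 13 (5 adjusted over the list alone, camera adjusted p = 0.000527; adjusted p = 0.569 with an estimated correlation), and Cd68 went from 70.2 to 31.3 TPM. MHC class I genes had 4 falls among 20 (4 adjusted over the list alone, camera adjusted p = 0.00261; adjusted p = 0.569 with an estimated correlation). Eosinophil markers had 4 falls and 1 rise among 8 (5 and 1 adjusted over the list alone, camera adjusted p = 0.00531; adjusted p = 0.569 with an estimated correlation), and Prg2 went from 108 to 9.13 TPM. Basophil and mast markers had 4 falls and 2 rises among 10 (5 and 2 adjusted over the list alone, camera adjusted p = 0.0116; adjusted p = 0.569 with an estimated correlation). The basophil protease Prss34 went from 121 to 20.0 TPM and the mast cell protease Cpa3 from 106 to 281. The eosinophil call ended with median-of-ratios (0.053) and quantile scaling (0.0652), removal of the length trend (0.0588), limma-voom (0.0819) and the immediate early covariate. The basophil call ended with quantile scaling (0.055), removal of the length trend (0.0717) and limma-voom (0.0611).

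Among cell cycle and metabolic lists, S phase genes had 6 falls among 30 (9 adjusted over the list alone) and a median of -0.24 (camera adjusted p = 2.24e-05; adjusted p = 0.624 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, went from 220 TPM (SD 20.3, n = 4) to 121 (SD 6.08, n = 4), while the proliferation marker Mki67 stood at 77.6 against 75.4. Nuclear oxidative phosphorylation genes had 2 falls among 79 (2 adjusted over the list alone) and a median of -0.15, or -0.09 without Idh2R172K replicate 4 (camera adjusted p = 2.1e-05; adjusted p = 0.857 with an estimated correlation), a call that ended with the immediate early covariate. The mitochondrial transcript list was not called (mt-Co1, 3461 to 6604 TPM). Genes of IDH and the TCA cycle had 7 falls and 2 rises among 41 (9 and 3 adjusted over the list alone, camera adjusted p = 0.0156; adjusted p = 0.869 with an estimated correlation). That call ended without Idh2R172K replicate 4 (0.093), with all number 4 libraries of WT and Idh left out, with quantile scaling (0.0931) and with the immediate early covariate. Genes of the TET, DNMT and base excision list had 5 rises among 21 (7 adjusted over the list alone; camera adjusted p = 0.193). They included Tet1 (0.53), Tet3 (0.37) and Dnmt3a (0.49). The calls ended without WT replicate 3 or Idh2R172K replicate 1 or 2 (Tet1, 0.0536 to 0.0781), without WT replicate 1, 2 or 3 or Idh2R172K replicate 1, 2 or 4 (Tet3, 0.0543 to 0.124), and without WT replicate 2 or Idh2R172K replicate 4 (Dnmt3a, 0.0606 and 0.0736). The interferon response list was not called (8 falls and 2 rises among 38, 9 and 3 adjusted over the list alone, camera adjusted p = 0.105). Its median of 0.06 differed in sign from its mean of -0.11, and Ifi47, an interferon-induced GTPase, went from 250 to 123 TPM.

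**Figure D3:**
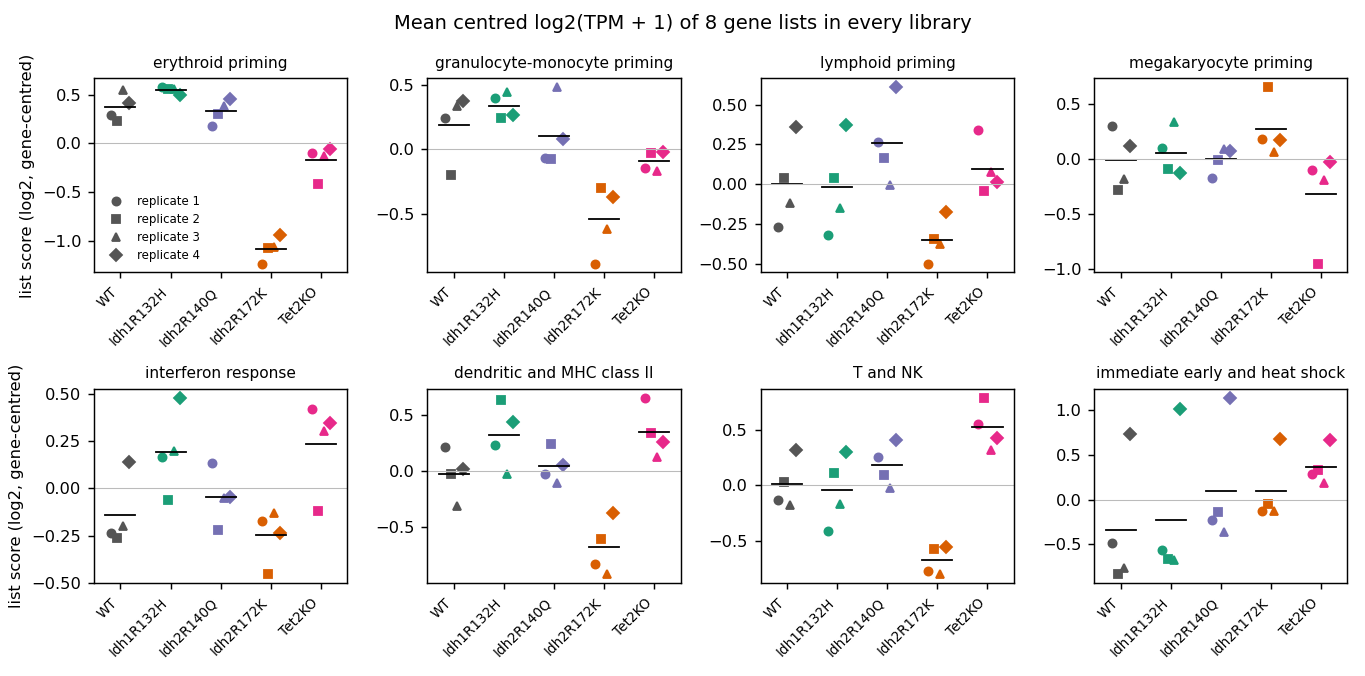
Scores of 8 lists chosen after seeing the data (mean over members of the gene-centred log2(TPM + 1), y axis) in each library, by group on the x axis, with the replicate number as the marker shape and the group mean as a line. The erythroid score ran from 0.23 to 0.55 in WT, -1.23 to -0.94 in Idh2R172K and -0.42 to -0.06 in Tet2KO, and the number 4 libraries of WT and the Idh groups stand high in the immediate early score.

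Tet2KO against WT asks how cells without the dioxygenase differ, with any effect of Cre included. Of the erythroid priming genes 14 of 23 fell here, by less than in Idh2R172K, and 12 of 38 interferon response genes rose. Neither list call held with an estimated correlation (adjusted p = 0.159 and 0.855), and the interferon score of Tet2KO replicate 2 lay inside the WT range. Il4 and Hmga2 were among the largest rises, and Sva, a secreted glycoprotein, stood near 0 TPM. Of 999 genes called, 712 were higher and 287 lower, 143 and 32 of them by at least 2-fold. Direction went with exon length, with a median of 1904 bp in higher, 4776 in lower and 3694.5 in all genes tested. This count turned on single libraries and settings. It was 504 without WT replicate 1, 266 without WT replicate 3, 351 without Tet2KO replicate 4, 45 in the fit of the 2 groups alone and 2648 with median-of-ratios scaling. The share of higher genes went from 71.3% to 42.9% with that scaling, 42.2% with quantile scaling, 58.5% after rescaling, 42.7% with limma-voom and 44.8% without the length trend. It went up to 80.8% with no filter, 83.6% with library weights, 87.9% without the number 4 libraries and 89.5% without these and Tet2KO replicate 2.

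Il4, a type 2 cytokine (ENSMUSG00000000869, chromosome 11, 53602982 to 53618669), rose by 1.64 ± 0.22 (adjusted p = 0.000894), from 1.58 TPM (SD 0.721, n = 4) to 6.84 (SD 0.574, n = 4). Hmga2, a chromatin protein of fetal and self-renewing cells (ENSMUSG00000056758, chromosome 10, 120361275 to 120476469), rose by 1.55 ± 0.21 (adjusted p = 0.000859), from 3.27 TPM (SD 0.393, n = 4) to 11.9 (SD 4.05, n = 4). Rises of small RNAs, where a few TPM are few reads, included Mir23a (2.39 to 11.1 TPM), Snord92 (6.63 to 19.3) and Mir3473d (0 to 3.30). Sva (ENSMUSG00000023289, chromosome 6, 42038394 to 42042851) fell by 3.27 ± 0.20 (adjusted p = 3.02e-08), from 8.95 TPM (SD 0.859, n = 4) to 0.0338 (SD 0.0675, n = 4). Rps6ka2, a ribosomal S6 kinase, went from 4.13 to 0.712 TPM, Hpse, the heparanase, from 37.6 to 14.8, Chdh from 35.1 to 9.42 and Ces2g from 49.6 to 20.1. The fit of the 2 groups ended the calls of Chdh (0.0662), Ces2g (0.0618) and Snord92, and removal of the length trend also ended that of Snord92.

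Other genes the rule named were less stable. The chemokine Ccl4 rose by 2.06 ± 0.52, and its call ended without WT replicate 1 (0.0795), WT replicate 3 (0.0853) or Tet2KO replicate 4 (0.0774). Gp5 and Vwf, both platelet genes, fell by 1.41 and 1.22. The calls ended without WT replicate 3 (Gp5, 0.0656) and without WT replicate 1 or 3 (Vwf, 0.0502 and 0.0517).

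Erythroid priming had 14 falls and 1 rise among 23 members in Tet2KO (16 and 1 adjusted over the list alone) and a median of -0.63 (camera adjusted p = 5.78e-11; adjusted p = 0.159 with an estimated correlation). Klf1 fell by 0.95 ± 0.12 (adjusted p = 0.000457), from 55.7 TPM (SD 6.28, n = 4) to 28.3 (SD 2.39, n = 4). Gata1 went from 49.0 TPM (SD 5.25, n = 4) to 29.5 (SD 3.80, n = 4) with an adjusted p of 0.00568, Sphk1 fell by 1.09 ± 0.14 and the erythroid membrane protein Ermap by 1.20 ± 0.18. The rise was Cnrip1 (0.69), named after its value was seen. Red cell markers went the other way in part, with 5 rises and 1 fall among 11 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0926, fry adjusted p = 0.0291). The globin gene Hbb-bs went from 9.31 TPM (SD 1.58, n = 4) to 21.1 (SD 1.47, n = 4) and Hba-a1 rose by 0.79 ± 0.18. Haem synthesis and iron genes had 6 falls and 2 rises among 26 (8 and 3 adjusted over the list alone; camera adjusted p = 0.0672), and Alas2, the erythroid enzyme of haem synthesis, rose by 0.71 ± 0.15. Calls of Gata1 (0.072), Ermap (0.0662), Hba-a1 (0.0963) and Alas2 (0.0624) ended in the fit of the 2 groups.

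Interferon response genes had 12 rises and no fall among 38 members in Tet2KO (19 rises adjusted over the list alone) and a median of 0.34 (camera adjusted p = 2.43e-05; adjusted p = 0.855 with an estimated correlation). Ifit3b rose from 0.785 TPM (SD 0.324, n = 4) to 2.24 (SD 0.420, n = 4), a call that ended in the fit of the 2 groups (0.0734). Rsad2 (0.61), Oasl1 (0.64) and Xaf1 (0.71), genes of antiviral defence, rose. The calls ended without WT replicate 1 (0.0671, 0.0683 and 0.0693), WT replicate 3 (0.0624, 0.0538 and 0.0856) or Tet2KO replicate 4 (0.0607, 0.0666 and 0.0607). For Oasl1 and Xaf1 they also ended without WT replicate 2 (0.0534 and 0.0585). By library, the score of this list was -0.12 in Tet2KO replicate 2 and 0.30 to 0.42 in the other Tet2KO libraries, and -0.26 to 0.14 in WT. Ly6a, which encodes the sort marker Sca1 and is on the HSC list, went from 168 TPM (SD 18.6, n = 4) to 292 (SD 39.1, n = 4), and Ifitm1, also on that list, from 963 TPM (SD 65.1, n = 4) to 1711 (SD 114, n = 4). The HSC list as a whole had 4 rises and 1 fall among 33 (5 and 1 adjusted over the list alone; camera adjusted p = 0.123), Procr stood at 39.2 TPM against 26.1 (SD 10.1, n = 4; adjusted p = 0.249), and Hlf at 69.7 against 72.6.

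Cell cycle lists were lower in Tet2KO, in large part through replicate 2. S phase had 3 falls among 30 (16 adjusted over the list alone) and a median of -0.34, or -0.17 without Tet2KO replicate 2 (camera adjusted p = 3.65e-05; adjusted p = 0.855 with an estimated correlation). Its score was -0.54 in Tet2KO replicate 2 and -0.13 to 0.01 in the other Tet2KO libraries. G2/M had 3 falls among 30 (4 adjusted over the list alone) and a median of -0.25, or -0.10 without Tet2KO replicate 2 and -0.11 without WT replicate 4 (camera adjusted p = 0.000146; adjusted p = 0.855 with an estimated correlation). Mki67 stood at 60.8 TPM against 75.4 (adjusted p = 0.165). No member of the DNA damage response list passed in limma, over all genes or adjusted over the list alone (median -0.23, camera adjusted p = 0.00375; adjusted p = 0.855 with an estimated correlation), and the list call ended with library weights. Most of that shift lay in Tet2KO replicate 2, with a score of -0.79 against -0.09 to 0.07 in the other Tet2KO libraries, and the median was -0.02 without it and -0.15 without WT replicate 4. Granulocyte-monocyte priming had 2 falls and 1 rise among 31 (3 and 2 adjusted over the list alone, camera adjusted p = 0.00482; adjusted p = 0.855 with an estimated correlation), and Hk3 went from 156 to 81.6 TPM. The list call ended without Tet2KO replicate 1 (0.0651) or 3 (0.0652), with quantile scaling (0.0868) and with the immediate early covariate. The Hk3 call ended in the fit of the 2 groups (0.08). Mpo stood at 2535 TPM against 3608 (adjusted p = 0.128) and Itga2b at 85.3 against 104 (adjusted p = 0.353).

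Marker lists of other cells and of handling moved with the Tet2KO group. T and NK markers had 2 rises among 9 (5 adjusted over the list alone, median 0.52, camera adjusted p = 0.00878; adjusted p = 0.855 with an estimated correlation), a call that ended without Tet2KO replicate 2 (0.107), with quantile scaling (0.0868), at a mean of at least 5 TPM and with library weights. Macrophage markers had 3 rises among 13 (5 adjusted over the list alone, median 0.33, camera adjusted p = 0.00626; adjusted p = 0.855 with an estimated correlation), a call that ended with quantile scaling (0.0686), with library weights and without the number 4 libraries of WT and Idh. Without Tet2KO replicate 2 that median was 0.53. Immediate early and heat shock genes had 3 rises among 26 (3 adjusted over the list alone, median 0.56, camera adjusted p = 0.0127; adjusted p = 0.855 with an estimated correlation), a call that ended without Tet2KO replicate 2 (0.199). The score of that list was 0.19 to 0.66 in the Tet2KO libraries, -0.83 to -0.49 in WT replicates 1 to 3 and 0.73 in WT replicate 4. Ribosomal protein genes had 1 rise among 85 (0 adjusted over the list alone by limma) and a median of 0.18 (camera adjusted p = 3.65e-05; adjusted p = 0.855 with an estimated correlation). The list turned to the opposite direction without Tet2KO replicate 2 (0.882, median 0.05), with library weights (0.0116) and without both Tet2KO replicate 2 and the number 4 libraries (6.92e-05). Its call ended without WT replicate 4 (0.142, median 0.12), without the number 4 libraries and without the length trend (0.455).

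Tet2KO against Idh2R172K asks whether loss of Tet2 and the Idh2 mutation, whose product 2-hydroxyglutarate inhibits TET enzymes, act on the same genes and in the same direction. Of the genes called in each against WT 322 were shared, with 200 higher in both, 91 lower in both, 30 lower in Idh2R172K and higher in Tet2KO, and 1 the reverse. Independent lists of these sizes would share 57.16, 21.04, 52.18 and 23.04 by chance. Both used the same WT libraries. In the same order the numbers were 276, 260, 70 and 25 with median-of-ratios and 219, 290, 66 and 42 with quantile scaling. They were 256, 238, 67 and 28 with limma-voom and 374, 83, 62 and 1 without the number 4 libraries. The balance of rises to falls turned on scaling. The overlap was 109 without WT replicate 3, 157 without Tet2KO replicate 4 and 200 without WT replicate 1. With separate WT libraries, replicates 1 and 2 for Idh2R172K and 3 and 4 for Tet2KO, 34 genes were higher in both, 43 lower in both, 9 lower in Idh2R172K and higher in Tet2KO and 0 the reverse, of 1253 and 324 genes called. Independent lists would share 13.91 in the same and 14.73 in opposite directions. With the WT libraries exchanged the numbers were 8, 4, 2 and 0, of 1344 and only 33 genes called, against 1.4 and 1.73.

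Hmga2 rose by 1.55 in both (direct adjusted p = 1). Erythroid genes fell further in Idh2R172K, Klf1 by 2.70 against 0.95 (direct adjusted p = 7.35e-09) and Gata1 by 2.26 against 0.72 (6.55e-08). So did Sphk1 by 2.83 against 1.09 (7.56e-08), Chdh by 4.33 against 1.82 (1.18e-05) and Ces2g by 3.48 against 1.30 (6.01e-07). Among the 31 genes of opposite direction were the basophil protease Prss34 (-2.64 in Idh2R172K, 0.91 in Tet2KO, direct adjusted p = 2.2e-08) and Oasl1 of the interferon list (-0.97 and 0.64, 8.18e-07). Ifi27l2a, another interferon-induced gene (-1.01 and 1.11, 6.52e-05), Gpx7 (-1.76 and 0.50, 1.23e-09), Bex1 (-1.73 and 0.72, 1.28e-08) and Ccni, the gene of the reverse kind (0.47 and -0.46), lie outside the naming rule and were chosen after their values were seen. The Tet2KO call of Prss34 ended without any WT replicate or without Tet2KO replicate 1, 3 or 4 (0.0505 to 0.12), and that of Oasl1 without WT replicate 1, 2 or 3 or Tet2KO replicate 4 (0.0534 to 0.0683).

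**Figure D4:**
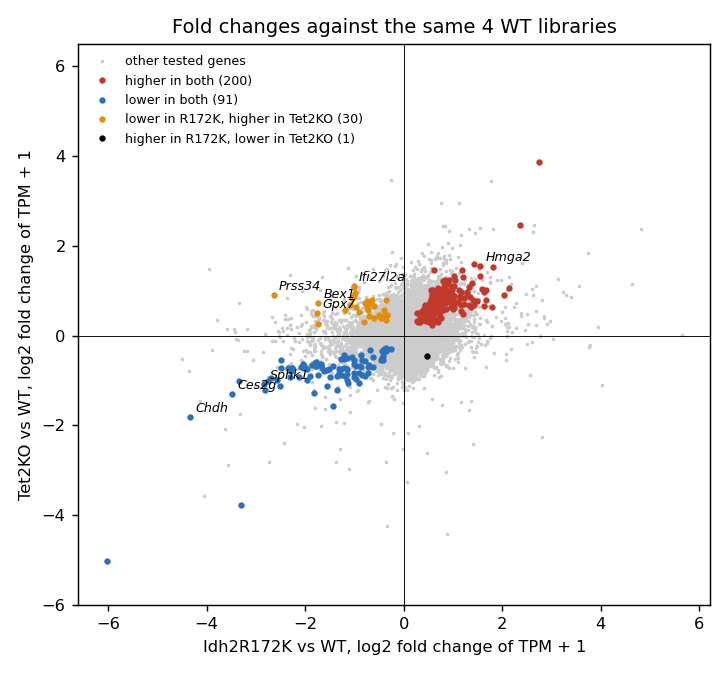
Log2 difference from WT in Idh2R172K (x axis) and Tet2KO (y axis) for each gene tested, from limma on log2(TPM + 1) with n = 4 libraries per group, with genes called in both coloured by direction (200, 91, 30 and 1) and 8 labels chosen after seeing the data. Hmga2 lies at 1.55 on both axes, and Prss34 at -2.64 and 0.91.

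Compared directly, Tet2KO and Idh2R172K differed in 3803 genes, 1684 higher and 2119 lower in Tet2KO. The fit of the 2 groups alone gave 1190 with the balance turned, 849 higher and 341 lower, as did library weights with 3207 and 2066 and the removal of the number 4 libraries with 2122 and 1308. It also turned without Idh2R172K replicate 2 or 4 or Tet2KO replicate 2 (50.3, 55.8 and 55.5% higher). Tet2KO was above Idh2R172K by 5.43 ± 0.57 in Ccl3 (133 TPM against 2.23), 4.14 ± 0.13 in Nr0b2, 4.06 ± 0.49 in Prg2, 3.98 ± 0.17 in Padi4 (35.6 against 1.27) and 3.74 ± 0.24 in Psma8. It was below in Perp by -4.02 ± 0.18 (5.11 against 94.8 TPM) and in the immunoglobulin genes Igkv3-5, Igkv14-126, Ighv6-6 and Igkv4-59, the last lost without Idh2R172K replicate 2 or Tet2KO replicate 2 (0.0649 and 0.0564). Erythroid priming was higher in Tet2KO in 16 of 23 members and lower in 2 (16 and 2 adjusted over the list alone, median 0.98, camera adjusted p = 1.74e-11; adjusted p = 0.135 with an estimated correlation). Interferon response was higher in 18 of 38 and lower in 1 (18 and 1 adjusted over the list alone, median 0.42, 2.06e-06; adjusted p = 0.519 with an estimated correlation). T and NK markers were higher in 6 of 9 (6 adjusted over the list alone, median 1.40, 1.21e-05; adjusted p = 0.135 with an estimated correlation). Dendritic and MHC class II markers were higher in 7 of 11 with 1 lower (8 and 1 adjusted over the list alone, 6.59e-05; adjusted p = 0.228 with an estimated correlation). Megakaryocyte priming was lower in 8 of 23 and higher in 2 (8 and 2 adjusted over the list alone, 0.0279; adjusted p = 0.802 with an estimated correlation), a call that ended without Idh2R172K replicate 1 (0.0597) or 2 (0.147), with the replicate block and with the immediate early covariate.

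The Idh1R132H and Idh2R140Q groups ask whether Tet2 loss resembles the weaker mutants. Across genes, which are not independent replicates, the differences from WT correlated at r = 0.290 between Idh2R172K and Tet2KO, 0.475 between Idh1R132H and Idh2R140Q, and 0.425 between Idh2R140Q and Idh2R172K. The values were 0.293 between Idh1R132H and Idh2R172K, 0.272 between Idh2R140Q and Tet2KO and 0.164 between Idh1R132H and Tet2KO. Groups simulated as unchanged gave medians of 0.493 to 0.527 because of the shared WT libraries. All 6 values lie inside their wide simulated limits (-0.0375 to 0.835 for Idh2R172K and Tet2KO). The covariance of Idh2R172K and Tet2KO, 0.0682, lay above its simulated limit of 0.0643, and that of the other pairs did not. The margin is small, as the covariance was 0.0602 without Idh2R172K replicate 1, 0.0632 without Tet2KO replicate 1 and 0.0629 with quantile scaling. With separate WT libraries for the groups of a pair, r was 0.0973 and 0.136 for Idh2R172K and Tet2KO and -0.174 to 0.164 for the others. Spearman's rho for Idh1R132H and Tet2KO was -0.105.

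Against Idh1R132H, Tet2KO differed in 1913 genes, 967 higher and 946 lower, and against Idh2R140Q in 1352, 574 higher and 778 lower. The share of higher genes went from 50.5% to 75.6% with library weights, 74.9% without the number 4 libraries and 38.5% with the immediate early covariate against Idh1R132H. Against Idh2R140Q it went from 42.5% to 73.6%, 77.0% and 40.2%, to 59.3% with no filter, and to 66.3% without Idh2R140Q replicate 4. Without single libraries the former count was 1077, 1071, 672 and 1254 without Idh1R132H replicate 1, 2, 3 or 4 and 942 without Tet2KO replicate 4. The latter was 431, 189 and 413 without Idh2R140Q replicate 2, 3 or 4, 2231, 790 and 177 without Tet2KO replicate 1, 2 or 4, and 4 in the fit of the 2 groups (Sva, Ifitm1, Gm14044 and Gm37068, the last 2 chosen after their values were seen). Il4 was higher in Tet2KO by 1.85 ± 0.22 against Idh1R132H, and stood at 6.84 TPM against 2.18 in Idh2R140Q. Sva was lower by -3.26 ± 0.20 and -3.20 ± 0.20, Rps6ka2 by -1.75 ± 0.21 and -1.51 ± 0.21, and Chdh by -1.81 ± 0.31 and -1.51 ± 0.31. Gp5 was lower against Idh1R132H by -1.80 ± 0.32, and Fcna was higher against Idh2R140Q at 34.2 TPM against 13.7. Erythroid priming was lower against Idh1R132H in 16 of 23 members and higher in 1 (18 and 1 adjusted over the list alone, camera adjusted p = 2.43e-12; adjusted p = 0.105 with an estimated correlation). Against Idh2R140Q it was lower in 12 of 23 (16 lower and 1 higher adjusted over the list alone, median -0.57, 7.08e-07; adjusted p = 0.765 with an estimated correlation). Interferon response was higher against Idh2R140Q in 8 of 38 (13 adjusted over the list alone, median 0.25, 3.56e-05; adjusted p = 0.793 with an estimated correlation).

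The Idh mutants were compared among themselves to ask whether the alleles differ. Idh2R172K differed from Idh1R132H in 1918 genes, 880 higher and 1038 lower, and from Idh2R140Q in 1489, 533 higher and 956 lower. Perp was higher in Idh2R172K by 3.60 and 3.74 (log2), Smagp by 3.08 against Idh1R132H and Cd200r4 by 2.98 against Idh2R140Q. Car1 was at 25.2 TPM in Idh2R172K and lower than in Idh1R132H by -4.38, Padi4 by -4.05 and -4.11, Chdh by -4.32 and -4.03, and Ccl3 by -4.13 and -4.40. Erythroid priming was lower in 21 of 23 members against Idh1R132H with 1 higher (21 and 1 adjusted over the list alone, median -1.42, camera adjusted p = 8.05e-30; adjusted p = 0.00214 with an estimated correlation). It was lower in 17 of 23 against Idh2R140Q with 1 higher (20 and 1 adjusted over the list alone, median -1.04, 3.51e-27; adjusted p = 0.00344 with an estimated correlation). Interferon response was lower against Idh1R132H in 15 of 38 (15 adjusted over the list alone, median -0.24, or -0.37 without Idh1R132H replicate 2, 7.93e-07; adjusted p = 0.44 with an estimated correlation). Lymphoid priming was lower against Idh2R140Q in 12 of 24 with 1 higher (13 and 2 adjusted over the list alone, 8.64e-08; adjusted p = 0.448 with an estimated correlation).

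Idh2R140Q and Idh1R132H differed in 1 gene (274 at an unadjusted p under 0.05), Fhl2, which was lower in Idh2R140Q by -1.35 ± 0.18 (adjusted p = 0.00983). The call ended without Idh1R132H replicate 2 (0.0746), Idh2R140Q replicate 2 (0.0748) or Idh2R140Q replicate 3 (0.074), with a pseudocount of 0.1 and in the fit of the 2 groups. No list member passed in limma, over all genes or adjusted over the list alone, in the lists that follow. As sets, erythroid priming was lower in Idh2R140Q with 4 of 23 members above 0 (camera adjusted p = 1.43e-17), a call that held with an estimated correlation (adjusted p = 0.0282). Interferon response had 3 of 38 members above 0 (1.05e-21; adjusted p = 0.0717 with an estimated correlation), and granulocyte-monocyte priming was lower (7.93e-15; adjusted p = 0.0717 with an estimated correlation). Lymphoid priming had 23 of 24 members above 0 (2.03e-08; adjusted p = 0.295 with an estimated correlation). B lineage markers were above 0 in 11 of 11 members (7.88e-08; adjusted p = 0.0717 with an estimated correlation) and eosinophil markers in 0 of 8 (1.36e-07; adjusted p = 0.0717 with an estimated correlation).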

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

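The tests chosen only after their result was seen are those of a few abundant genes and of other cells in Tet2KO replicate 2, of a Tet2KO group effect, and of scaling, red cells and a single library for the erythroid falls. The tests of gene length, of a batch and of other splits of the libraries were written before. The tests of a few abundant genes, of other cells, of red cells and of a group effect were redefined after earlier versions had been seen. The earlier versions pointed the same way, and that of red cells in Idh2R172K (median -0.159) also left the matter open.

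Tet2KO replicate 2 stood apart, as its Kit RNA, which encodes a sort marker, was 97.9 TPM against 334 to 457 in the other 3 Tet2KO libraries, or 24.0% of their mean, and the top gene took 20.0% of its TPM, while 14105 genes reached 1 TPM. A few genes taking most of the TPM are argued against, since after rescaling the shortest of 4 length classes of genes still lay 0.749 (log2) above the longest and Kit was still at 27.9%. Mature cells as the cause of the low Kit are argued against, since members of the HSC and priming lists kept a median of 79% of their level (100.4% in granulocyte-monocyte, 85.3% in lymphoid and 79.2% in erythroid priming, but 51.4% in HSC and 52.8% in megakaryocyte priming), while the largest rise among 10 marker lists was 0.357, in T and NK, over a drop of all genes by 0.405, and a small share of such cells stays open. Gene length remains a candidate explanation, since the deviation correlated with exon length across genes at a Spearman rho of -0.45 against -0.305 to 0.408 in the other libraries, with class medians of 0.028, -0.319, -0.587 and -0.705. What made long genes low in this library is not known from the labels, and a property of these mice was not tested.

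Genes called in Tet2KO against WT met a second structure, as WT replicate 4 shared high immediate early RNA with Tet2KO: the median of that list was 0.733 in Tet2KO over WT replicates 1 to 3, and -0.22 in Tet2KO replicates 1, 3 and 4 over WT replicate 4. A handling or library batch that Tet2KO shares with the number 4 libraries cannot be told apart from the group for these genes, since outside that list the Tet2KO difference correlated with the number 4 difference of the Idh groups at only r = 0.181 across genes (0.255 without Tet2KO replicate 2, and 0.535 for WT replicate 4 itself), and the labels give no batch. A group effect may hold for part of the genes, since of 54 genes called with Tet2KO replicates 1 and 2 against WT replicates 1 to 3, 94.4% kept their sign in Tet2KO replicates 3 and 4 over WT replicate 4, with medians of 0.857 and -0.632 there. An earlier form of that test, on the 999 called genes themselves, was circular and gave 100%. Among groups simulated as unchanged, Tet2KO gave calls in 18 of 100 draws and up to 2458 genes, against 8 draws and up to 3 genes for Idh2R172K.

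Erythroid priming genes were lower in Idh2R172K and, by less, in Tet2KO, where the list call (adjusted p = 0.159) and the direct list difference (0.135) did not hold with an estimated correlation. Scaling of the TPM is argued against in both, since the median nearest 0 over 3 scalings was -1.227 in Idh2R172K and -0.621 in Tet2KO. Fewer mature red cells in the sort are argued against in both, since the summed globin RNA fell by only 4.49 TPM from 53.7 in Idh2R172K while Klf1 and Gata1 together fell by 87.5, and changed by -53.32 on the same scale, a higher level, in Tet2KO. A single deviating library is argued against in Tet2KO by a median of -0.496 without Tet2KO replicate 2. A shift in the mix of progenitors within the gate, or in each cell, was not tested and may equally underlie both falls.

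The 35 splits of 8 libraries into 4 and 4 were fitted in the same way. Only the real split gave as many in Idh2R172K against WT (2177 genes, highest other 1), which argues against chance. So it was for Tet2KO against Idh1R132H (1913, 1), Idh2R140Q (1352, 1) and Idh2R172K (3803, 3). As 1 of 35 is the lowest share possible and unchanged Tet2KO draws gave up to 2458 genes, chance is not excluded for Tet2KO. Against WT (999, 1125) 2 splits gave as many. In Idh2R140Q against WT (0, 2) no gene was called, so the splits say nothing. The split with 1125 genes set WT replicates 1 to 3 and Tet2KO replicate 2 against WT replicate 4 and Tet2KO replicates 1, 3 and 4, which points to a structure of the samples. In the 4 comparisons where the replicate numbers pair the libraries, only the 8 splits that part all 4 pairs are alike in this respect, which is too few for a share under 0.05. There the real value and the highest other were 1 and 0 in Idh1R132H against WT, 1 and 0 in Idh2R140Q against Idh1R132H, 1918 and 0 in Idh2R172K against Idh1R132H, and 1489 and 0 in Idh2R172K against Idh2R140Q. Splits that keep pairs together gave at most 0, 0, 1 and 1.

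By Dixon's limit, which about 1 in 20 groups passes by chance, 14 of 85 library measures and single genes held a deviating library (4.2 by chance). Idh2R140Q replicate 2 had 45.04 M reads (M, 1000000). Idh1R132H replicate 4 had 7.66% in the top gene and 10.8% in rRNA-like genes, and Tet2KO replicate 2 had 23.8% in rRNA-like genes. Mean correlations with the own group were 0.964 in WT replicate 4, 0.968 in Idh1R132H replicate 4 and 0.960 in Idh2R140Q replicate 4. Idh2 stood at 624 TPM in Idh1R132H replicate 4, Procr at 45.8 in Idh2R172K replicate 4, Mpo at 2573 in WT replicate 2 and 5392 in Idh2R140Q replicate 3, and Itga2b at 133 in WT replicate 4. Of 170 list scores 17 held a deviating library (8.5 by chance), 13 of them in number 4 libraries of WT or the Idh groups and 2 in Tet2KO replicate 2.

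Differences between mutant groups were tested directly. Tet2KO and Idh2R172K differed in opposite senses from WT in 31 genes (95 with median-of-ratios scaling, 108 with quantile scaling, 74 with TPM rescaled, 95 with limma-voom, 88 without the length trend), and directly in interferon response (camera adjusted p = 2.06e-06), megakaryocyte priming (0.0279, ending without Idh2R172K replicate 1 at 0.0597 or 2 at 0.147), dendritic and MHC class II markers (6.59e-05) and T and NK markers (1.21e-05), none with an estimated correlation (adjusted p = 0.519, 0.802, 0.228 and 0.135 with an estimated correlation).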

How the results depend on the processing

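Alternatives added only after seeing the data were the length trend removal, limma-voom, pool sex, the immediate early covariate and both removals of several libraries, and the others were planned. The genes named by the rule gave 1991 results on the same side of the threshold when 1 library was left out, 336 that were no longer called and 1 newly called, and 205 and 85 stayed and were lost in the fit of the 2 groups. Of the list results 2440 stayed when 1 library was left out, 147 were lost, 127 gained and 6 reversed, and 141 calls were lost with an estimated correlation. Scalings moved the genes in Idh2R140Q against WT by a median of -0.11 (quantile), and other settings moved those in Tet2KO against WT by medians of 0.15 (arrayWeights), -0.10 (immediate early covariate), 0.16 (number 4 libraries and Tet2KO replicate 2 left out) and 0.10 (without Tet2KO replicate 2). At a depth of 35.2 to 45.04 M reads (M, 1000000) and n = 4, 35.7% and 34.9% of 1.5-fold changes were found in data simulated with independent genes. No other depth or n was simulated. Except for fewer genes tested under a stricter filter and fewer libraries left in, the cause was not tested for any value that follows.

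Counts of called genes are given here where they left the range of 1.5 times the reported count. With a pseudocount of 0.1, Idh2R140Q against Idh1R132H gave 0 genes in limma, and the correlations of Tet2KO with Idh1R132H and with Idh2R140Q were 0.286 and 0.375. With no filter on low values, Idh1R132H against WT gave 2 genes (Fhl2 and Gm14248), Idh2R140Q against WT 2 (Hapln3 and Gm14248), Idh2R140Q against Idh1R132H 2 (Fhl2 and Hapln3) and Tet2KO against Idh2R140Q 668. Overlaps were 1 gene for Idh1R132H with Idh2R140Q, with Idh2R172K and with Tet2KO, 2 for Idh2R140Q with Idh2R172K and 1 for Idh2R140Q with Tet2KO. Of these genes all but Fhl2 were chosen after their values were seen. With a mean TPM of at least 5, Idh1R132H against WT gave 0 and Idh2R140Q against Idh1R132H 0, as Fhl2 was filtered out. Idh2R172K gave 1371 against WT, 1242 against Idh1R132H and 894 against Idh2R140Q, Tet2KO against WT 517, and the overlap of Idh2R172K and Tet2KO was 168.

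Scaling raised the Tet2KO counts. Against WT, Idh1R132H and Idh2R140Q in turn, Tet2KO gave 2648, 3479 and 2759 genes with median-of-ratios scaling, 2492, 3459 and 2992 with quantile normalization, and 1840, 2897 and 2279 with TPM rescaled. They were 2320, 3117 and 2151 with the exon length trend removed, 2539, 3396 and 2703 with limma-voom, and 1802, 3677 and 3289 with the immediate early score as a covariate. The overlap of Idh2R172K and Tet2KO was 631 with median-of-ratios scaling, 617 with quantile normalization, 534 with TPM rescaled, 669 with the exon length trend removed and 589 with limma-voom. With the exon length trend removed Idh2R172K gave 2882 genes against Idh1R132H and 2299 against Idh2R140Q.

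With only the 2 groups compared, Idh1R132H against WT gave 0 genes, and Tet2KO gave 45 against WT, 548 against Idh1R132H, 4 against Idh2R140Q and 1190 against Idh2R172K. With limma arrayWeights, Idh2R172K gave 4586 against WT, 4567 against Idh1R132H and 2734 against Idh2R140Q. Tet2KO gave 5231 against WT, 6133 against Idh1R132H and 3342 against Idh2R140Q, all with limma arrayWeights, which for Idh2R140Q against Idh1R132H gave 5 (Fhl2, Acadl, Ndn, Hist1h4m and Gm14044, all but Fhl2 chosen after their values were seen). With the replicate block, Idh1R132H against WT gave 2 (Fhl2 and Plbd1, the latter chosen after its value was seen), and Tet2KO 2485 against WT, 3550 against Idh1R132H and 2993 against Idh2R140Q. Where the numbers pair the libraries, in Idh1R132H against WT, Idh2R140Q against Idh1R132H, Idh2R172K against Idh1R132H and Idh2R172K against Idh2R140Q, the replicate block gave 2, 1, 2764 and 2076 genes. It ended 3 list calls in the first of these and added NF-kB in the second (0.0144) and the last (0.0364), and changed no other call there.

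With the number 4 libraries of WT and Idh groups left out, Tet2KO against WT gave 2082 genes and the overlap of Idh2R172K and Tet2KO was 520. With Tet2KO replicate 2 left out as well, Idh2R172K gave 4641 genes against WT, 3815 against Idh1R132H and 2884 against Idh2R140Q. Tet2KO then gave 4515 against WT, 4633 against Idh1R132H and 3382 against Idh2R140Q, the overlap of Idh2R172K and Tet2KO was 2031, and that of Idh1R132H and Tet2KO 1.

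Leaving out each library in turn gave 266 to 1391 genes in Tet2KO against WT, 672 to 2467 against Idh1R132H, 177 to 2231 against Idh2R140Q, and 0 to 3 in Idh2R140Q against Idh1R132H. The overlap of Idh2R172K and Tet2KO ranged from 109 to 471, and those of Idh1R132H with Idh2R172K and with Tet2KO from 0 to 1. Correlations across genes ranged from 0.354 to 0.593 for Idh1R132H and Idh2R140Q, 0.124 to 0.289 for Idh1R132H and Tet2KO and 0.192 to 0.383 for Idh2R140Q and Tet2KO.

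Lists that reversed are given with their adjusted p. With limma arrayWeights these were ribosomal proteins in Tet2KO against WT (0.0116), oxidative phosphorylation in Tet2KO against Idh1R132H (0.0397) and histones in Tet2KO against Idh2R140Q (0.0474). With the exon length trend removed they were oxidative phosphorylation in Tet2KO against Idh1R132H (0.753) and histones in Tet2KO against Idh2R140Q (0.593). With the immediate early score as a covariate they were the immediate early list in Idh2R140Q against WT (0.818), from which the score was made, and ribosomal proteins in Idh2R140Q against Idh1R132H (0.0239). With the number 4 libraries and Tet2KO replicate 2 left out they were G2/M in Idh2R140Q against WT (0.901), ribosomal proteins in Tet2KO against WT (6.92e-05) and Idh1R132H (0.88), oxidative phosphorylation in Tet2KO against Idh1R132H (0.0287) and histones in Tet2KO against Idh2R140Q (0.0442). Without Tet2KO replicate 2 they were ribosomal proteins against WT (0.882) and histones against Idh2R140Q (0.486). Without Idh1R132H replicate 4 it was oxidative phosphorylation against WT (0.372), without Idh2R140Q replicate 3 mature neutrophil markers against WT (0.208), and without Idh2R140Q replicate 4 ribosomal proteins (0.000374) and oxidative phosphorylation (0.943) against Idh1R132H. Over all single libraries left out, the adjusted p ranged from 4.55e-19 to 0.372 for oxidative phosphorylation in Idh1R132H against WT, 1.09e-06 to 0.208 for mature neutrophil in Idh2R140Q against WT, and 2.73e-09 to 0.882 for ribosomal proteins in Tet2KO against WT. It ranged from 3.9e-05 to 0.486 for histones in Tet2KO against Idh2R140Q, and in Idh2R140Q against Idh1R132H from 1.7e-14 to 0.781 for ribosomal proteins and 4.09e-24 to 0.943 for oxidative phosphorylation.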

Other observations

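The tests in this part were planned in advance, while counts out of 25 alternatives include the 6 added after seeing the data. Several lists were not described above. In Tet2KO against WT, genes of IDH and the TCA cycle had 1 rise and 1 fall among 41 (1 and 7 adjusted over the list alone) and a median of -0.16, or -0.05 without Tet2KO replicate 2 (camera adjusted p = 0.00118; adjusted p = 0.855 with an estimated correlation), a call that ended with quantile scaling (0.0686). The rise was Glul, glutamine synthetase (0.39), whose call ended without WT replicate 3 (0.0815) or Tet2KO replicate 4 (0.0548). HIF and glycolysis genes had 2 falls among 32 (2 adjusted over the list alone, camera adjusted p = 0.00482; adjusted p = 0.855 with an estimated correlation), a call that ended with the immediate early covariate, added after seeing the data. The fall of this list sat in Tet2KO replicate 2, with a score of -0.62 against -0.05 to 0.08 in the other Tet2KO libraries, and its median went from -0.16 to -0.03 without that library. Megakaryocyte priming had 1 fall among 23 (2 adjusted over the list alone, camera adjusted p = 0.0152; adjusted p = 0.855 with an estimated correlation), ending in 9 of 25 alternatives, among them without WT replicate 1 (0.089) or Tet2KO replicate 2 (0.142). Dendritic and MHC class II markers had 1 rise among 11 (1 adjusted over the list alone, median 0.50, camera adjusted p = 0.0483; adjusted p = 0.855 with an estimated correlation), ending in 15 of 25 alternatives, among them without WT replicate 3 (0.0952) or 4 (0.142) or Tet2KO replicate 1 (0.112) or 2 (0.258). Replication-dependent histones had 3 rises among 56, with Hist1h3d going from 13.0 to 27.3 TPM (camera adjusted p = 0.0745), and transcription factors 4 rises and 2 falls among 46, with Ikzf2 rising by 0.79 ± 0.15 (camera adjusted p = 0.768). Both gene calls ended in the fit of the 2 groups (0.0778 and 0.0734).

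In Idh2R172K against WT, ribosomal proteins had 2 falls among 85 (1 adjusted over the list alone) and a median of -0.07 (-0.14 to 0.01 without WT replicate 1, 2 or 4 or Idh2R172K replicate 1 or 4; camera adjusted p = 0.00437; adjusted p = 0.869 with an estimated correlation), a call that ended without WT replicate 1 (0.0505) or 2 (0.182) or Idh2R172K replicate 4 (0.5). Rps4l, a ribosomal protein paralog, went from 43.9 to 4.24 TPM. Targets of p53 had 4 rises and 1 fall among 21 (camera adjusted p = 0.174), HIF and glycolysis genes 6 falls and 2 rises among 32 (0.429), other 2-oxoglutarate dioxygenases 5 falls and 3 rises among 44 (0.583), and immediate early genes 3 rises and 1 fall among 26 (0.414), with Socs3 going from 22.8 to 87.8 TPM. The other lists not called had camera adjusted p of 0.105 to 0.823.

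Lists that were not called in Tet2KO against WT had camera adjusted p of 0.0672 to 0.932.

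In Idh1R132H against WT, where no list member passed over all genes, the other called lists were higher for eosinophil markers (8 of 8 above 0, median 0.62, and 0.34 to 1.00 without WT replicate 1 or 2 or Idh1R132H replicate 1 or 4, camera adjusted p = 0.00025), mature neutrophil (0.00825), granulocyte-monocyte priming (0.0128), red cell (0.0248) and transcription factors (0.0386), and lower for ribosomal proteins (5.62e-11), oxidative phosphorylation (2.78e-05), plasma cell (0.0124) and B lineage (0.0305). With an estimated correlation the adjusted p were 0.311, 0.84, 0.867, 0.302, 0.949, 0.84, 0.867, 0.791 and 0.791. Each ended without at least 1 library. These were Idh1R132H replicate 1 for eosinophil (0.187), Idh1R132H replicate 1 or WT replicate 2 or 4 for mature neutrophil (0.378, 0.195 and 0.133). They were Idh1R132H replicate 1 or 3 or WT replicate 2 for granulocyte-monocyte priming (0.208, 0.391 and 0.922), and Idh1R132H replicate 1, 2 or 3 or WT replicate 2 or 4 for red cell (0.0758, 0.124, 0.207, 0.074 and 0.352). They were any Idh1R132H replicate but 3 or any WT replicate but 1 for transcription factors (0.0671 to 0.261), and Idh1R132H replicate 4 for ribosomal proteins (0.585). They were WT replicate 2 for oxidative phosphorylation (0.332, and reversed without Idh1R132H replicate 4, 0.372), Idh1R132H replicate 2 or 4 or WT replicate 1 for plasma cell (0.07, 0.23 and 0.467), and Idh1R132H replicate 1, 3 or 4 or WT replicate 1 or 2 for B lineage (0.0774 to 0.222). The replicate block also ended the calls of transcription factors (0.0616), B lineage (0.0528) and red cell (0.0782). Lists that were not called had camera adjusted p of 0.17 to 0.963.

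In Idh2R140Q against WT the other called lists were higher for B lineage (median 0.44, camera adjusted p = 0.011), immediate early genes (0.0219), mature neutrophil (0.0267) and transcription factors (0.0292), and lower for erythroid priming (0.000944), IDH and the TCA cycle (0.011), G2/M (0.0285) and macrophage (0.039). With an estimated correlation the adjusted p were 0.777 for B lineage and erythroid priming and 0.857 for the others. The test asks for a difference from other genes, so the IDH list was called lower with a median near 0, and the G2/M median was also near 0 with a mean of opposite sign. The calls ended without Idh2R140Q replicate 1 or 2 or WT replicate 3 or 4 for B lineage (0.0517, 0.177, 0.0684 and 0.077), and Idh2R140Q replicate 4 or WT replicate 1, 2 or 3 for immediate early genes (0.707, 0.0571, 0.181 and 0.304). They ended without WT replicate 2 or 4 for mature neutrophil (0.201 and 0.192, reversed without Idh2R140Q replicate 3, 0.208), and Idh2R140Q replicate 2 or 4 or WT replicate 2, 3 or 4 for transcription factors (0.0528 to 0.222). They ended without WT replicate 3 for erythroid priming (0.213), Idh2R140Q replicate 2 or 4 or WT replicate 3 for the IDH list (0.101, 0.101 and 0.112), Idh2R140Q replicate 2 or WT replicate 3 or 4 for G2/M (0.69, 0.112 and 0.929), and Idh2R140Q replicate 2, 3 or 4 or WT replicate 1, 2 or 3 for macrophage (0.0594 to 0.939). Lists that were not called had camera adjusted p of 0.0578 to 0.972.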
